A study of Mus musculus with 46 samples.

How the data were processed

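Total RNA from stromal cells of mouse brachial lymph nodes was measured on 46 Affymetrix Mouse Gene ST arrays, 1 colour each, with a biotin label. The cells came from female C57BL/6 mice that were naive or had been infected on the skin with herpes simplex virus 3, 6 or 30 days earlier. Nodes were digested with collagenase, DNase and dispase, and CD45-negative cells were sorted on gp38 (the product of Pdpn) and CD31 (the product of Pecam1). Fibroblastic reticular cells (FRC) were gp38-positive and CD31-negative, lymphatic endothelial cells (LEC) carried both, and blood endothelial cells (BEC) were CD31-positive and gp38-negative.

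The authors processed the arrays with RMA, which corrects background, normalizes between arrays and summarizes each probe set, and the deposited values are on the log2 scale. The RMA version, the software and the arrays that were normalized together are not stated. The values were used as deposited. They ran from 2.24 to 14.05, with array medians from 5.46 to 5.80. Arrays carry no count depth, so the number of arrays per group limits the precision.

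The table held 34760 probe sets. Of these, 21640 mapped to 1 gene symbol in the probe table and were used, 1321 mapped to several symbols, and 11799 were not in the probe table. A probe set was kept if its value lay above the median of its array in at least 3 arrays, which left 14480 probe sets. Where a gene had several, the probe set with the highest mean over all arrays stood for it, as for 716 genes. The result was 13239 genes. Symbols were checked against a reference gene table that held 21553 of the probe sets' gene identifiers, and 0 symbols changed.

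One linear model with a mean for each of the 12 groups was fitted to all 46 arrays with limma 3.58.1 in R 4.3.3, using lmFit and eBayes, with 34 residual degrees of freedom. Each of the 3 cell types was compared at each day with its naive arrays, day 6 was compared with day 3, and the naive cell types were compared with each other. P-values were adjusted by Benjamini-Hochberg over the genes of each comparison, and a gene was called at an adjusted p under 0.05. All tests were two-sided. The moderated F-test of the interaction asked for each day whether the change from naive differed between cell types. Log2 differences are given with their standard error (SE), and group levels with their SD. Whether arrays came from separate animals is not stated, so the p-values measure the spread between samples, pooled over cell types.

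Gene lists were taken from general knowledge of lymph node stroma and viral infection, and 33 had at least 3 measured members. Programs were interferon-stimulated antiviral genes, interferon-gamma-inducible GTPases and related genes (such as Cxcl9), MHC class I and class II presentation, DNA replication and G1/S, mitosis and G2/M, homeostatic chemokines and lymphocyte survival factors, inflammatory chemokines and cytokines, NF-kappaB and TNF signalling, complement and acute phase, extracellular matrix, matrix proteases and inhibitors, contractile apparatus, angiogenic signalling, high endothelial venule genes, endoplasmic reticulum (ER) chaperones and cholesterol biosynthesis. Genes that respond to handling or hour were immediate early and dissociation-induced genes and circadian clock genes. Marker lists covered FRC, lymphatic, blood and pan-endothelial cells, pericytes and smooth muscle, B cells, plasma cells, T and NK cells, macrophages and dendritic cells, neutrophils, platelets and erythroid cells, adipocytes, skeletal muscle and keratinocytes. Each list was tested against all other genes with limma's camera at its preset correlation of 0.01, adjusted over the 297 tests of 33 lists in 9 comparisons with naive, and again with a correlation estimated from the data. The interaction of each list was tested the same way in another 297 tests.

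Named genes followed a rule. It took the 8 largest rises and 8 largest falls among called genes of each comparison, passing over predicted genes, small RNAs, histone clusters and immunoglobulin or T cell receptor segments. It added up to 4 called members of each list with at least 3 called, the 8 genes with the smallest adjusted p in each interaction test among those differing at least 2-fold, up to 8 genes per direction that were called at both day 6 and day 30, and the sort genes Pdpn, Pecam1, Ptprc and Cr2. The comparisons, lists, thresholds and naming rule were fixed before the data were examined, as were the alternatives of no filter, a stricter filter at the 75th percentile, probe set means, an intensity trend, array weights, median centring, cyclic loess, separate fits per cell type, the estimated correlation, replicate number as a block and the leaving out of each array. A further 2 alternatives were chosen after the data were seen: leaving out the 2 arrays with the narrowest spread of values, and the SD of each array's values as a covariate.

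The pipeline was tested on simulated data with 50 changed genes per size. For FRC at day 6 against naive it recovered 76% of changes of 1 log2 unit and 98% of changes of 2. For LEC and BEC at day 30 against naive it recovered 54% of changes of 1 log2 unit, and 94% and 92% of changes of 2. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.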

Results

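The 46 arrays fell into 12 groups of cell type by time. FRC had 5 naive arrays and 4 each at days 3, 6 and 30. LEC had 3 naive arrays, 4 at day 3, 4 at day 6 and 3 at day 30. BEC had 4 naive arrays, 4 at day 3, 4 at day 6 and 3 at day 30. The series title asks how lymph node stromal cells respond to primary and secondary infection; the groups here cover 1 infection followed over time. Correlations between 2 arrays of a group ran from 0.827 to 0.970. The first principal component held 39.4% of the variance and the second 17.0%, and the next held 9.5%.

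The sort genes followed the gates. Pdpn stood at 10.12 ± 0.51 (log2, SD, n = 5) in naive FRC, 9.49 ± 0.37 (n = 3) in naive LEC and 5.54 ± 0.14 (n = 4) in naive BEC. Pecam1 stood at 6.46 ± 0.38 in naive FRC, 10.75 ± 0.54 in naive LEC and 12.19 ± 0.12 in naive BEC. Ptprc, which encodes CD45, ranged from 4.67 to 5.90 in group mean, and lay above the array median in 0 FRC and LEC arrays. In BEC it lay above that median in 3 of 4 naive arrays (5.90 ± 0.41), 1 of 4 at day 3 (5.30 ± 0.37), 0 of 4 at day 6 (5.00 ± 0.36) and 2 of 3 at day 30 (5.83 ± 0.24). Cr2, which encodes the complement receptor CD21, ranged from 4.43 to 6.28, the highest in LEC at day 30 (6.28 ± 0.79, n = 3).

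The spread of values within an array differed between arrays, and the naive groups of FRC and LEC each held 1 array of narrow spread. The SD over all probe sets was 1.83 in FRC naive replicate 5 and 1.81 in LEC naive replicate 3, against 1.92 to 2.10 elsewhere and 2.04 to 2.06 in naive BEC. Genes of the other gates also differed between arrays. The median of 11 endothelial genes was 8.10 in FRC day 6 replicate 4 and 5.37 to 5.83 in the other FRC day 6 arrays. The median of 82 FRC-specific genes was 6.24 in BEC day 6 replicate 3 and 5.79 in replicate 4, against 5.30 and 5.28 in replicates 1 and 2.

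**Figure D1:**
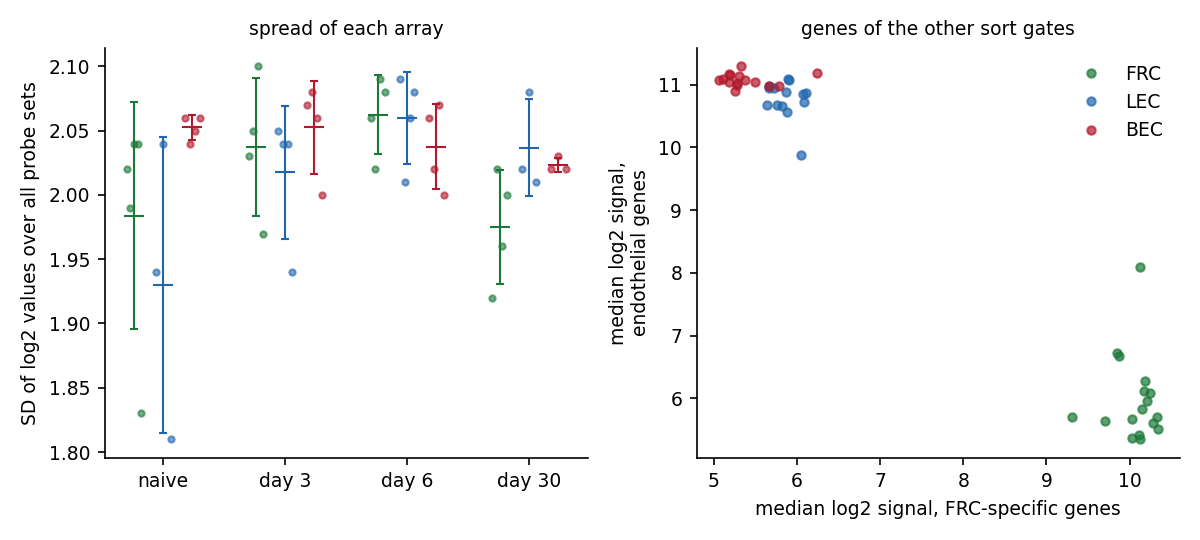
Left, the SD of log2 values over all probe sets for each array (points), with the mean and SD of each group (bars), by time and cell type; FRC naive replicate 5 (1.83) and LEC naive replicate 3 (1.81) lie lowest. Right, the median log2 signal of FRC-specific genes against that of endothelial genes for each array, where FRC day 6 replicate 4 lies at 8.10 on the endothelial axis.

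The 3 naive cell types differed widely, which gives the background for the responses. In naive FRC, Dpt (dermatopontin) was 6.44 ± 0.54 log2 units higher than in LEC, Ccl11 was 5.85 ± 0.42 higher, and the complement genes C1s1 (5.81 ± 0.42) and C4b (5.77 ± 0.24) were higher too. LEC exceeded FRC in Prox1, the transcription factor of lymphatic identity (-6.03 ± 0.37), the scavenger receptor Stab2 (-5.55 ± 0.23) and Mmrn1 (-5.79 ± 0.43). Against BEC, naive FRC were higher in the B cell chemokine Cxcl13 (7.44 ± 0.63), Dcn (7.24 ± 0.51) and Ccl7 (6.49 ± 0.41), and lower in Flt1 (-6.32 ± 0.24) and Kdr (-6.10 ± 0.25), both receptors of vascular endothelial growth factor. LEC exceeded BEC in Prox1 (5.67 ± 0.39), Stab2 (5.61 ± 0.24) and Sema3d (5.83 ± 0.34), and BEC exceeded LEC in Nrp1 (-5.84 ± 0.28), Flt1 (-5.62 ± 0.28) and Cd34 (-5.39 ± 0.50).

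Between naive FRC and LEC, 3111 genes were called, 1652 higher and 1459 lower in FRC, and 1670 of them differed at least 2-fold. Between FRC and BEC, 3350 were called (1611 higher and 1739 lower in FRC), and between LEC and BEC 2765 (1217 higher and 1548 lower in LEC). Each of the 16 genes named per comparison kept its call when any 1 array was left out. The LEC against BEC count was 1491 without LEC naive replicate 3 and 4389 without LEC naive replicate 2, and 1640 without the 2 arrays of narrow spread.

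At day 3 after infection, FRC (4 arrays against 5 naive) changed in genes of several kinds. Saa3, an acute-phase serum amyloid, rose by 4.26 ± 0.39 log2 units (adjusted p = 5.06e-10). The interferon-induced Ifi27l2a rose by 2.41 ± 0.19, the adhesion molecule Chl1 by 2.95 ± 0.25 and the fatty acid binding protein Fabp7 by 2.76 ± 0.34. Among genes that fell were 2 cytochromes P450, Cyp2f2 (-4.06 ± 0.29, adjusted p = 1.06e-12) and Cyp2e1 (-2.52 ± 0.28), the methyltransferase Inmt (-2.10 ± 0.24), the neutrophil chemokine Cxcl5 (-2.58 ± 0.41) and Igfbp3 (-1.62 ± 0.25). For every gene whose rise or fall is named in these comparisons, each array of the later group lay on the called side of the earlier group's mean.

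Several of the fixed lists shifted in FRC at day 3. Of 33 interferon-stimulated antiviral genes, 13 rose and 20 did not pass, and 18 were higher when adjusted over the list alone; the list shifted upward (camera adjusted p = 1.1e-13). Examples were Bst2 (1.19 ± 0.15), which tethers virus particles to the cell, the nucleic acid sensor Zbp1 (1.45 ± 0.23) and Oasl2 (1.07 ± 0.20). Of 25 DNA replication and G1/S genes, 13 rose and 17 were higher adjusted over the list alone (adjusted p = 2.7e-16), among them Mcm6 (1.80 ± 0.24), Uhrf1 (1.81 ± 0.25) and Rrm2 (1.82 ± 0.31). Of 28 mitosis and G2/M genes, 11 rose and 18 were higher adjusted over the list alone (adjusted p = 6.6e-16; adjusted p = 0.071 with an estimated correlation), with Top2a at 2.93 ± 0.34 and Mki67 at 2.32 ± 0.34. Interferon-gamma-inducible GTPases and related genes had 7 of 15 members up, and 8 adjusted over the list alone (adjusted p = 6.1e-05; adjusted p = 0.11 with an estimated correlation), including Irgm1 (1.58 ± 0.25) and the chemokine Cxcl9 (1.10 ± 0.24).

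MHC class I presentation had 4 of 14 members up in FRC at day 3, and 8 adjusted over the list alone (adjusted p = 6.5e-05; adjusted p = 0.11 with an estimated correlation), among them the immunoproteasome subunit Psmb8 (0.82 ± 0.19). Of 6 class II genes, 2 rose, and 4 adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.083 with an estimated correlation). Contractile genes had 4 of 14 up, such as Flna (0.62 ± 0.15), and 5 adjusted over the list alone (adjusted p = 0.0012; adjusted p = 0.18 with an estimated correlation). ER chaperones had 4 of 19 up, such as Pdia4 (0.96 ± 0.21), and 11 adjusted over the list alone (adjusted p = 2e-06; adjusted p = 0.25 with an estimated correlation). Immediate early and dissociation-induced genes moved the other way: 8 of 17 fell, such as Junb (-0.65 ± 0.15), and 11 adjusted over the list alone (adjusted p = 3.8e-10; adjusted p = 0.078 with an estimated correlation). Complement and acute-phase genes had 2 of 11 up, and 3 adjusted over the list alone (adjusted p = 0.0042; adjusted p = 0.31 with an estimated correlation); that call ended without FRC naive replicate 5 (adjusted p = 0.051).

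In all, 734 genes were called in FRC at day 3, 454 up and 280 down, 303 of them at least 2-fold. The split was 421 up and 465 down after cyclic loess scaling. Of 57 named genes, 37 kept their call when any 1 array was left out. Without FRC day 3 replicate 1 the count was 366, and without the 2 arrays of narrow spread it was 679, of which 532 were shared with the full set.

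At day 6, more FRC genes were called than at day 3. Fabp7 rose by 4.51 ± 0.34 log2 units (adjusted p = 1.3e-12), Saa3 by 3.75 ± 0.39, Mpeg1, which encodes the pore-forming perforin-2, by 3.45 ± 0.27, the proteoglycan versican (Vcan) by 3.23 ± 0.33, and Thy1 by 3.11 ± 0.52. Cyp2f2 fell by 5.26 on the log2 scale (SE 0.29, adjusted p = 8.1e-17), Inmt by 3.72 (SE 0.24) and Cyp2e1 by 3.01 (SE 0.28). Transcription factors that respond to stimulation also fell, among them Fosl1 (-2.80 ± 0.30) and Nr4a3 (-2.46 ± 0.27). The neutrophil proteins S100a8 (-3.78 ± 0.75) and S100a9 (-3.47 ± 0.71) were lower too. The mean of the neutrophil markers varied between naive FRC arrays, from 6.33 in replicate 5 to 9.19 in replicate 2. Whether the sorted FRC themselves made this RNA was not tested.

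Interferon and antigen presentation lists shifted upward in FRC at day 6, each also with an estimated correlation. Of 33 antiviral genes, 19 rose and 14 did not pass, with 26 higher and 1 lower adjusted over the list alone (adjusted p = 4e-21). Zbp1 rose by 2.58 ± 0.23, Parp9 by 2.01 ± 0.23 and Bst2 by 1.52 ± 0.15. Interferon-gamma-inducible GTPases and related genes had 11 of 15 up, the same count adjusted over the list alone (adjusted p = 3.1e-11), with Gbp4 at 3.09 ± 0.37 and Irgm1 at 2.62 ± 0.25. Class I presentation had 9 of 14 up, and 10 adjusted over the list alone (adjusted p = 2.7e-08), including the peptide transporter Tap1 (1.41 ± 0.18) and Psmb9 (1.55 ± 0.24). Class II presentation had 5 of 6 up, also adjusted over the list alone (adjusted p = 2.8e-09), with H2-Aa at 2.61 ± 0.33, H2-DMa at 2.42 ± 0.26 and Cd74 at 1.98 ± 0.19.

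Proliferation, matrix and contractile lists also shifted in FRC at day 6. Of 28 mitosis and G2/M genes, 26 rose, and 27 adjusted over the list alone (adjusted p = 5e-30), with Mki67 at 3.08 ± 0.34 and Tpx2 at 2.27 ± 0.24. DNA replication and G1/S had 8 of 25 up, and 9 adjusted over the list alone (adjusted p = 1.2e-05; adjusted p = 0.17 with an estimated correlation). Of 37 matrix genes, 11 rose and 1 fell, with 16 and 2 adjusted over the list alone (adjusted p = 3.7e-05; adjusted p = 0.16 with an estimated correlation); Col12a1 rose by 2.51 ± 0.22, Col5a2 by 1.31 ± 0.17 and elastin (Eln) by 1.10 ± 0.18. Contractile genes had 9 of 14 up, and 10 adjusted over the list alone (adjusted p = 7.7e-06; adjusted p = 0.066 with an estimated correlation), including smooth muscle actin (Acta2, 1.70 ± 0.42) and Tagln (1.33 ± 0.24). Pericyte and smooth muscle markers had 4 of 9 up and 1 down beside them, without a shift as a list (median 0.58, adjusted p = 0.24). Their mean was 9.05 to 9.26 in the day 6 arrays and 8.42 to 8.94 in the naive ones. Complement and acute-phase genes had 3 of 11 up, and 5 adjusted over the list alone (adjusted p = 0.0016; adjusted p = 0.26 with an estimated correlation), among them Lcn2 (1.74 ± 0.37) and complement factor B (Cfb, 0.79 ± 0.16). ER chaperones had 7 of 19 up and 1 down, with 8 and 1 adjusted over the list alone (adjusted p = 0.0029; adjusted p = 0.52 with an estimated correlation). That shift was lost without FRC naive replicate 5 (adjusted p = 0.059) and after cyclic loess scaling (adjusted p = 0.15).

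Other lists moved downward in FRC at day 6. Immediate early and dissociation-induced genes had 16 of 17 down, and 17 adjusted over the list alone (adjusted p = 1.1e-19, held with an estimated correlation), with Klf4 at -1.61 ± 0.19, Junb at -1.17 ± 0.15 and Fosb at -1.39 ± 0.21. Clock genes had 5 of 13 down, and 6 adjusted over the list alone (adjusted p = 0.00073; adjusted p = 0.067 with an estimated correlation), such as Per1 (-1.18 ± 0.19), which also responds to stimulation. All 3 measured neutrophil markers fell, also adjusted over the list alone (adjusted p = 0.0014; adjusted p = 0.077 with an estimated correlation). Adipocyte markers had 2 of 4 down, also adjusted over the list alone (adjusted p = 0.015; adjusted p = 0.18 with an estimated correlation). FRC day 6 replicate 4, with its raised endothelial genes, is 1 of the 4 arrays behind these values.

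At day 6, 1763 genes were called in FRC, 1064 up and 699 down, 729 of them at least 2-fold. The split was 896 up and 870 down after cyclic loess scaling and 702 up and 819 down with the SD of each array as a covariate. Without the 2 arrays of narrow spread, 1529 were called, of which 1334 were shared. Of 88 named genes, 77 kept their call when any 1 array was left out.

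From day 3 to day 6, FRC raised Aoc1, which encodes diamine oxidase (2.23 ± 0.14, adjusted p = 4.31e-14), Fam162b (3.04 ± 0.27), the class II chaperone subunit H2-DMa (2.28 ± 0.28) and Fabp7 (1.75 ± 0.36). Inmt fell further (-1.62 ± 0.25), with the transporter Abca8a (-1.51 ± 0.18) and Gli1, a transcription factor of the hedgehog pathway (-1.39 ± 0.20). In this comparison 105 genes were called, 75 up and 30 down. The count was 163 without FRC day 3 replicate 3. Here 12 of 16 named genes kept their call when any 1 array was left out.

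At day 30, 42 genes were called in FRC against naive (4 arrays against 5), 14 of them also called in the same direction at day 6. The Wnt antagonist Sfrp4 rose by 2.33 ± 0.37 log2 units (adjusted p = 0.00138), Gpnmb by 1.31 ± 0.23, the matrix protein Cilp by 1.28 ± 0.23, Fgf2 by 1.19 ± 0.21 and the flippase Atp8b1 by 1.07 ± 0.20. Pleiotrophin (Ptn) fell by 1.64 (SE 0.26), the receptors Adgrg2 by 1.63 (SE 0.28) and Lpar4 by 1.56 (SE 0.31), and Fosl1 by 1.57 (SE 0.30). Each of these kept its call when any 1 array was left out, as did 10 of the 24 named genes. A fit of FRC arrays alone called 2 genes in all. Kdr, an endothelial gene, also rose (1.29; adjusted p = 0.091 without FRC day 30 replicate 1), and Pecam1 stood at 7.59 ± 0.84 against 6.46 ± 0.38 in naive FRC.

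The pan-endothelial list shifted upward in FRC at day 30 with 1 of 12 members up, and 5 adjusted over the list alone (median 0.36, adjusted p = 2.1e-05; adjusted p = 0.11 with an estimated correlation); the median was 0.55 without FRC naive replicate 5 (adjusted p = 0.00011). Class II genes had 0 of 6 called by limma, 2 adjusted over the list alone (median 0.47, adjusted p = 0.00066; adjusted p = 0.069 with an estimated correlation). ER chaperones moved downward with 0 of 19 called (median -0.19, adjusted p = 0.0029; adjusted p = 0.52 with an estimated correlation), with a median of -0.30 without FRC naive replicate 5 (adjusted p = 4.6e-06), -0.10 without FRC naive replicate 4 (adjusted p = 0.019), -0.12 without FRC day 30 replicate 3 (adjusted p = 0.017) and -0.10 after cyclic loess scaling (adjusted p = 0.024). Antiviral genes shifted upward with 0 of 33 called (median 0.25, adjusted p = 0.0055; adjusted p = 0.45 with an estimated correlation), a shift lost without FRC naive replicate 5 or without FRC day 30 replicate 4 (adjusted p up to 0.074). Cholesterol synthesis genes moved downward with 0 of 15 called and 1 adjusted over the list alone (adjusted p = 0.0097; adjusted p = 0.18 with an estimated correlation), lost without FRC naive replicate 1 or FRC day 30 replicate 1 (up to 0.072). Neutrophil markers moved downward with 0 of 3 called (adjusted p = 0.011; adjusted p = 0.17 with an estimated correlation), lost without FRC naive replicate 2 or FRC day 30 replicate 1 (up to 0.058). Clock genes (adjusted p = 0.026; adjusted p = 0.25 with an estimated correlation) and blood endothelial markers (adjusted p = 0.047; adjusted p = 0.26 with an estimated correlation) moved upward, and each was lost when any of 5 arrays was left out: FRC naive replicates 3, 4 and 5 and day 30 replicates 3 and 4 for the clock genes (up to 0.45), and FRC naive replicates 1, 2 and 4 and day 30 replicates 1 and 3 for the endothelial markers (up to 0.15).

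Of the 42 genes called in FRC at day 30, 26 were up and 16 down. The split was 28 up and 25 down after cyclic loess scaling and 48 up and 92 down, in 140 genes, without the 2 arrays of narrow spread, of which 39 were shared. The count was 91 without FRC naive replicate 5 and 25 without FRC day 30 replicate 3.

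In LEC at day 3 (4 arrays against 3 naive), the named rises included 3 chemokines. Ccl20, the chemokine ligand of CCR6, rose by 3.16 ± 0.31 log2 units (adjusted p = 2.04e-08), and Cxcl9, a ligand of CXCR3, by 2.49 ± 0.28. The C1 inhibitor Serping1 rose by 2.56 ± 0.35, lipocalin Lcn2 by 2.79 ± 0.42, the antibacterial lectin Reg3g by 2.83 ± 0.56, Ms4a4d by 3.15 ± 0.41 and Ccl5 by 2.15 ± 0.42. Ccin fell by 1.30 (SE 0.23) and Npas3 by 1.24 (SE 0.25). Thbs1, which encodes the matrix protein thrombospondin, rose by 1.23 ± 0.19 and the basement membrane collagen Col4a1 by 1.17 ± 0.19.

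Of 33 antiviral genes, 12 rose in LEC at day 3, and 26 adjusted over the list alone (adjusted p = 2.9e-23, held with an estimated correlation); Irf7 rose by 2.11 ± 0.29, Ifit2 by 2.14 ± 0.35 and the RNA sensor Ifih1 by 1.61 ± 0.26. Interferon-gamma-inducible GTPases and related genes had 6 of 15 up, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 8.6e-08, held), and complement and acute-phase genes had 3 of 11 up, and 6 adjusted over the list alone (adjusted p = 2.2e-07, held). Class I presentation had 1 of 14 up, and 8 adjusted over the list alone (adjusted p = 2e-06; adjusted p = 0.056 with an estimated correlation). Mitosis and G2/M genes had 4 of 28 up, such as Top2a (2.13 ± 0.38), and 11 adjusted over the list alone (adjusted p = 1.1e-10; adjusted p = 0.17 with an estimated correlation). DNA replication and G1/S had 1 of 25 up, and 3 adjusted over the list alone (adjusted p = 0.00079; adjusted p = 0.32 with an estimated correlation). ER chaperones shifted upward with 0 of 19 called and 11 adjusted over the list alone (adjusted p = 1.3e-06; adjusted p = 0.24 with an estimated correlation).

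A further 3 lists passed in LEC at day 3, each with calls lost when single arrays were left out. Inflammatory chemokines and cytokines shifted upward with 2 of 17 up, also adjusted over the list alone (adjusted p = 0.026; adjusted p = 0.35 with an estimated correlation), lost without any 1 of LEC naive replicates 2 and 3 and LEC day 3 replicates 1 and 3 (up to 0.16) and without the 2 arrays of narrow spread (0.15). Immediate early and dissociation-induced genes moved downward with 0 of 17 called (adjusted p = 0.017; adjusted p = 0.60 with an estimated correlation), lost without any 1 of LEC naive replicates 1 and 2 and LEC day 3 replicate 4 (up to 0.42), but stronger without the 2 arrays of narrow spread (median -0.33, adjusted p = 3.5e-07). T and NK cell markers moved downward with 0 of 6 called and 1 adjusted over the list alone (adjusted p = 0.036; adjusted p = 0.35 with an estimated correlation), lost without any 1 of LEC naive replicates 1 and 3 and LEC day 3 replicates 1 and 4 (up to 0.40) and without the 2 arrays of narrow spread (0.37).

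In LEC at day 3, 225 genes were called, 184 up and 41 down. The split was 88 up and 53 down after cyclic loess scaling, and without the 2 arrays of narrow spread 66 were called, of which 61 were shared. Of 35 named genes, 17 kept their call when any 1 array was left out. The count moved with each of the 7 arrays: it was 128, 1434 and 51 without LEC naive replicates 1, 2 and 3, and 109, 148, 92 and 466 without LEC day 3 replicates 1 to 4.

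By day 6, LEC had raised carbonic anhydrase Car4 by 4.49 ± 0.32 log2 units (adjusted p = 1.15e-12), Serping1 by 4.11 ± 0.35, Ms4a4d by 4.11 ± 0.41, the interferon-induced Ifi205 by 4.22 ± 0.47 and Ube2ql1 by 3.33 ± 0.25. Among the genes that fell were the potassium channel Kcnj2 at -2.85 ± 0.35, the glutamate receptor subunit Gria3 at -2.33 ± 0.30 and the acetylcholine receptor subunit Chrnb4 at -2.29 ± 0.32. The growth factor Bmp2 fell by 2.06 (SE 0.37). These genes kept their calls without any 1 array and without the 2 arrays of narrow spread. Of the 89 named genes, 64 did the first and 76 the second.

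Of 33 antiviral genes, 32 rose in LEC at day 6, the same count adjusted over the list alone (adjusted p = 6.4e-28), including Rsad2 (2.28 ± 0.23), Irf7 (2.81 ± 0.29) and Zbp1 (2.55 ± 0.27). Interferon-gamma-inducible GTPases and related genes had 11 of 15 up, also adjusted over the list alone (adjusted p = 9e-13), with Gbp4 at 3.74 ± 0.42 and Cxcl9 at 2.84 ± 0.28. Class I presentation had 10 of 14 up, and 12 adjusted over the list alone (adjusted p = 3.4e-09), with Tap1 at 1.36 ± 0.20. Class II presentation had 5 of 6 up, also adjusted over the list alone (adjusted p = 7e-07), with H2-Aa at 2.83 ± 0.37 and H2-Ab1 at 2.78 ± 0.34. These 4 shifts held with an estimated correlation. Mitosis and G2/M genes had 25 of 28 up, also adjusted over the list alone (adjusted p = 2.6e-16; adjusted p = 0.069 with an estimated correlation), with Top2a at 2.77 ± 0.38 and Anln at 2.45 ± 0.39. DNA replication and G1/S had 4 of 25 up, such as Mcm6 (1.52 ± 0.28), and 7 adjusted over the list alone (adjusted p = 0.0029; adjusted p = 0.40 with an estimated correlation).

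Matrix genes had 16 of 37 up and 3 down in LEC at day 6, with 16 and 6 adjusted over the list alone (adjusted p = 0.0043; adjusted p = 0.37 with an estimated correlation). Thbs1 rose by 2.39 ± 0.19, Col4a1 by 2.03 ± 0.19 and the laminin chain Lamc1 by 1.16 ± 0.16; the list call ended without LEC naive replicate 2 (adjusted p = 0.076) and after cyclic loess scaling (adjusted p = 0.10). FRC markers had 3 of 15 up beside them (median 0.14, adjusted p = 0.21; 0.39 and 0.016 without the 2 arrays of narrow spread). Complement and acute-phase genes had 6 of 11 up, and 7 adjusted over the list alone (adjusted p = 2.9e-05; adjusted p = 0.11 with an estimated correlation). Pan-endothelial markers had 3 of 12 up, also adjusted over the list alone (adjusted p = 0.0075; adjusted p = 0.36 with an estimated correlation), such as endoglin (Eng, 0.87 ± 0.15), and were not called after cyclic loess scaling (adjusted p = 0.33). ER chaperones had 8 of 19 up, and 10 adjusted over the list alone (adjusted p = 0.00046; adjusted p = 0.43 with an estimated correlation; adjusted p = 0.29 after cyclic loess scaling). Immediate early and dissociation-induced genes had 6 of 17 down and 1 up, with 11 and 1 adjusted over the list alone (adjusted p = 4.4e-05; adjusted p = 0.31 with an estimated correlation), including Nr4a1 (-1.61 ± 0.39) and Atf3 (-0.81 ± 0.19). Some blood cell lists moved downward. Platelet and erythroid markers had 2 of 5 down, and 3 adjusted over the list alone (adjusted p = 0.023; adjusted p = 0.071 with an estimated correlation), lost without LEC naive replicate 2 (0.19). B cell markers had 1 of 8 down, and 2 adjusted over the list alone (adjusted p = 0.033; adjusted p = 0.31 with an estimated correlation), lost without any 1 of LEC naive replicates 1 and 3 and LEC day 6 replicate 4 (up to 0.095). T and NK cell markers had 1 of 6 down, also adjusted over the list alone (adjusted p = 0.039; adjusted p = 0.36 with an estimated correlation), lost without any 1 of LEC naive replicate 3 and LEC day 6 replicates 1 and 3 (up to 0.20).

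In LEC at day 6, 2320 genes were called, 1366 up and 954 down, 901 of them at least 2-fold. The split was 731 up and 801 down after cyclic loess scaling, and without the 2 arrays of narrow spread 874 were called, 588 up and 286 down, of which 815 were shared. The count was 1486, 4253 and 734 without LEC naive replicates 1, 2 and 3, 1334 without LEC day 6 replicate 1 and 1321 without LEC day 6 replicate 4.

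From day 3 to day 6, LEC raised Car4 (4.01 ± 0.30, adjusted p = 3.85e-12), Acod1, which makes itaconate (2.59 ± 0.26), the scavenger receptor Olr1 (2.67 ± 0.32), H2-Ab1 (2.54 ± 0.32) and H2-Aa (2.52 ± 0.34). Kcnj2 fell by 2.97 (SE 0.32), Coch by 2.48 (SE 0.25) and the endopeptidase Mme by 1.99 (SE 0.43). This comparison uses no naive array; 295 genes were called, 177 up and 118 down. Of these, 13 of the 16 named genes kept their call when any 1 array was left out.

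At day 30, 34 LEC genes were called (26 up, 8 down), and Ccl20 was still raised (2.10 ± 0.33, adjusted p = 0.00243, 3 arrays against 3 naive). It alone of 16 named genes kept its call without any 1 array, and stood at 1.80 without the 2 arrays of narrow spread (adjusted p = 0.024). A fit of LEC arrays alone called 0 genes. Ms4a4d rose by 2.14 ± 0.43 (adjusted p up to 0.15 without any 1 of LEC naive replicates 1 and 3 and day 30 replicates 1 and 2), and Ccin fell by 1.49 (SE 0.25; adjusted p = 0.060 without LEC naive replicate 1).

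Of 33 antiviral genes, 2 rose in LEC at day 30, and 7 adjusted over the list alone (median 0.49, adjusted p = 2.6e-06; adjusted p = 0.14 with an estimated correlation). Class I presentation shifted upward with 0 of 14 called and 3 adjusted over the list alone (median 0.33, adjusted p = 0.0034; adjusted p = 0.27 with an estimated correlation), but its median was -0.02 after cyclic loess scaling (adjusted p = 0.51). Complement and acute-phase genes had 1 of 11 up, and 4 adjusted over the list alone (median 0.50, adjusted p = 0.0016; adjusted p = 0.26 with an estimated correlation). The remaining 4 shifts were lost without LEC naive replicate 3. One was interferon-gamma-inducible GTPases and related genes (adjusted p = 0.045; adjusted p = 0.50 with an estimated correlation), also lost without day 30 replicate 1 (up to 0.74). The ER chaperones were another (adjusted p = 0.042; adjusted p = 0.65 with an estimated correlation), also lost without day 30 replicate 2 (up to 0.99) and with a median of 0.31 that became -0.03 after cyclic loess scaling. The others were the T and NK cell markers, downward (adjusted p = 0.0052; adjusted p = 0.18 with an estimated correlation; 0.064 without that array), and the adipocyte markers, downward (adjusted p = 0.045; adjusted p = 0.29 with an estimated correlation), also lost without day 30 replicates 1 or 2 (up to 0.25).

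The LEC count at day 30 was 24 up and 15 down after cyclic loess scaling and 16 without the 2 arrays of narrow spread, of which 8 were shared. It was 8, 2030 and 13 without LEC naive replicates 1, 2 and 3, and 3 and 4 without LEC day 30 replicates 1 and 2.

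In BEC at day 3 (4 arrays against 4), 26 genes were called. Mctp1, a membrane protein with calcium-binding domains, rose by 2.48 ± 0.19 log2 units (adjusted p = 7.29e-12), Ms4a6d by 2.34 ± 0.31, Serping1 by 1.86 ± 0.33 and the prostaglandin transporter Slco2a1 by 1.59 ± 0.23. Prostaglandin D synthase (Ptgds) fell by 1.57 (SE 0.18, adjusted p = 3.18e-07) and the phosphodiesterase Pde1c by 1.11 (SE 0.19). These 6 of the 14 named genes kept their calls when any 1 array was left out. The other 8 lost theirs without at least 1 array.

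Lists shifted in BEC at day 3 with few members called. DNA replication and G1/S had 1 of 25 up, and 12 adjusted over the list alone (median 0.56, adjusted p = 1.8e-15), and the interferon-gamma-inducible GTPases and related genes had 0 of 15 called and 5 adjusted over the list alone (median 0.58, adjusted p = 1e-07); both held with an estimated correlation. Mitosis and G2/M genes had 0 of 28 called and 5 adjusted over the list alone (median 0.50, adjusted p = 2e-11; adjusted p = 0.16 with an estimated correlation), and antiviral genes 1 of 33 and 2 (median 0.29, adjusted p = 3.2e-06; adjusted p = 0.15 with an estimated correlation). Contractile genes had 0 of 14 called and 7 adjusted over the list alone (adjusted p = 3.4e-06; adjusted p = 0.056 with an estimated correlation), matrix genes 0 of 37 and 2 (adjusted p = 4.5e-05; adjusted p = 0.16 with an estimated correlation), and pericyte and smooth muscle markers 0 of 9 and 2 (adjusted p = 6e-05; adjusted p = 0.053 with an estimated correlation), all upward. FRC markers moved upward with 0 of 15 called (adjusted p = 0.0074; adjusted p = 0.46 with an estimated correlation), lost without BEC day 3 replicate 3 (0.18), the array whose FRC-specific genes stood highest of the 4 (median 5.67 against 5.11 to 5.26).

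Downward shifts in BEC at day 3 had no member called over all genes. They were immediate early and dissociation-induced genes (0 of 17, median -0.31, adjusted p = 2.7e-08; adjusted p = 0.13 with an estimated correlation), NF-kappaB and TNF signalling genes (0 of 20, median -0.24, adjusted p = 0.00022; adjusted p = 0.069 with an estimated correlation) and B cell markers (0 of 8, and 1 adjusted over the list alone, adjusted p = 0.00046; adjusted p = 0.071 with an estimated correlation). Inflammatory chemokines and cytokines also moved downward (0 of 17, and 1 adjusted over the list alone, adjusted p = 0.020; adjusted p = 0.32 with an estimated correlation), lost without any 1 of BEC naive replicate 1 and BEC day 3 replicates 3 and 4 (up to 0.12).

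In BEC at day 3, 26 genes were called by limma, 18 up and 8 down, and 894 had an unadjusted p under 0.05. The split was 27 up and 19 down after cyclic loess scaling, and 42 genes were called without the 2 arrays of narrow spread, neither of them BEC. The count was 15 without BEC naive replicate 2 and 15 without BEC day 3 replicate 3.

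At day 6, BEC raised Ms4a6d by 4.05 ± 0.31 log2 units (adjusted p = 2.55e-12), Serping1 by 3.84 ± 0.33, Vcan by 2.94 ± 0.34 and Mctp1 by 2.91 ± 0.19. Cxcl13, an FRC marker 7.44 higher in naive FRC than in naive BEC, rose by 3.16 ± 0.67. It stood at 9.35 and 8.18 in BEC day 6 replicates 3 and 4, whose FRC-specific genes were highest, at 7.10 and 5.68 in replicates 1 and 2, and at 9.28 in BEC day 3 replicate 3. Ptgds fell by 2.38 (SE 0.18), the lipid carrier Apoe by 2.06 (SE 0.20), the latent TGF-beta binding protein Ltbp2 by 2.12 (SE 0.21), the granulocyte growth factor Csf3 by 2.76 (SE 0.36), the chemokine Cxcl2 by 2.07 (SE 0.46) and the transcription factor Egr2 by 2.54 (SE 0.41).

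Mitosis and G2/M genes showed the smallest adjusted p of the lists in BEC at day 6, with 26 of 28 up and all 28 adjusted over the list alone (median 1.79, adjusted p = 9.8e-65); Top2a rose by 2.96 ± 0.35 and Cenpe by 1.99 ± 0.24. DNA replication and G1/S had 8 of 25 up, and 18 adjusted over the list alone (adjusted p = 1.7e-17), such as Uhrf1 (1.20 ± 0.27). Antiviral genes had 15 of 33 up, and 25 adjusted over the list alone (adjusted p = 8e-29), with Ifi27l2a at 2.31 ± 0.20 and Zbp1 at 2.17 ± 0.25. Interferon-gamma-inducible GTPases and related genes had 12 of 15 up, and 13 adjusted over the list alone (adjusted p = 6.4e-29), with Batf2 at 2.59 ± 0.30, Gbp5 at 2.37 ± 0.31 and Cxcl9 at 1.95 ± 0.26. Class I presentation had 4 of 14 up, and 8 adjusted over the list alone (adjusted p = 1.3e-08), with Tap1 at 1.39 ± 0.19. Class II presentation had 6 of 6 up, also adjusted over the list alone (adjusted p = 5.8e-15), with H2-Ab1 at 1.76 ± 0.32 and Cd74 at 1.47 ± 0.20. All 6 shifts held with an estimated correlation.

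Matrix genes had 10 of 37 up in BEC at day 6, and 16 adjusted over the list alone (adjusted p = 6.1e-15, held with an estimated correlation), including biglycan (Bgn, 1.91 ± 0.24), fibronectin (Fn1, 1.57 ± 0.26) and Col18a1 (1.10 ± 0.21). FRC markers moved upward beside them, with 2 of 15 up and 7 adjusted over the list alone (median 0.55, adjusted p = 2.4e-08; adjusted p = 0.069 with an estimated correlation), as did pericyte and smooth muscle markers (2 of 9 up, also adjusted over the list alone; adjusted p = 0.00092; adjusted p = 0.10 with an estimated correlation) and contractile genes (3 of 14 up, also adjusted over the list alone; adjusted p = 0.0044; adjusted p = 0.27 with an estimated correlation). Over 82 FRC-specific genes the median change was 0.29, and the 2 BEC day 6 arrays with the highest FRC-specific medians were replicates 3 (6.24) and 4 (5.79). Complement and acute-phase genes had 3 of 11 up, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0029; adjusted p = 0.29 with an estimated correlation).

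Immediate early and dissociation-induced genes had 10 of 17 down in BEC at day 6, and 13 adjusted over the list alone (adjusted p = 1.6e-17, held with an estimated correlation), with Fos at -0.99 ± 0.20 and Junb at -0.86 ± 0.15. NF-kappaB and TNF signalling genes had 4 of 20 down, such as Tnfaip3 (-1.25 ± 0.23), and 5 adjusted over the list alone (adjusted p = 8.2e-05; adjusted p = 0.056 with an estimated correlation). Inflammatory chemokines and cytokines had 3 of 17 down, among them Cxcl1 (-1.35 ± 0.22), with 4 lower and 1 higher adjusted over the list alone (adjusted p = 0.042; adjusted p = 0.40 with an estimated correlation), lost without any 1 of BEC naive replicates 1 and 3 and BEC day 6 replicates 1 and 2 (up to 0.14).

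In BEC at day 6, 474 genes were called, 263 up and 211 down, 277 of them at least 2-fold. Without the 2 arrays of narrow spread all 474 were again called, among 557. In all, 49 of 61 named genes kept their call when any 1 array was left out.

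From day 3 to day 6, BEC raised Prr11 (2.17 ± 0.31, adjusted p = 0.00011), the mitotic cyclin Ccnb2 (2.15 ± 0.38) and Anln (2.06 ± 0.36), with H2-DMa (1.89 ± 0.28), Serping1 (1.98 ± 0.33) and Gja5, the connexin of arterial endothelium (1.87 ± 0.29). Egr2 (-2.20 ± 0.41), Esm1, which encodes endocan (-1.38 ± 0.25), and the endothelin receptor Ednrb (-1.39 ± 0.28) fell. In this comparison 110 genes were called, 79 up and 31 down. There 10 of 16 named genes kept their call when any 1 array was left out. The count was 72, 65 and 72 without BEC day 3 replicates 1, 2 and 4, and 73 and 70 without BEC day 6 replicates 1 and 2.

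At day 30, 0 genes were called by limma in BEC against naive (3 arrays against 4), and 644 had an unadjusted p under 0.05. Of the fixed lists, 4 shifted, with 0 members called in each. ER chaperones moved downward (median -0.14, adjusted p = 0.0037; adjusted p = 0.54 with an estimated correlation; 0.15 after cyclic loess scaling) and FRC markers upward, with 1 adjusted over the list alone (median 0.33, adjusted p = 0.0034; adjusted p = 0.40 with an estimated correlation). Matrix genes moved upward (adjusted p = 0.026; adjusted p = 0.51 with an estimated correlation; up to 0.11 without BEC naive replicate 2 or BEC day 30 replicate 1), as did clock genes, with 1 adjusted over the list alone (adjusted p = 0.033; adjusted p = 0.27 with an estimated correlation; up to 0.82 without any 1 of BEC naive replicates 2 and 4 and BEC day 30 replicate 3). The gene count was 2 without BEC day 30 replicate 3 and 1 without the 2 arrays of narrow spread.

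**Figure D2:**
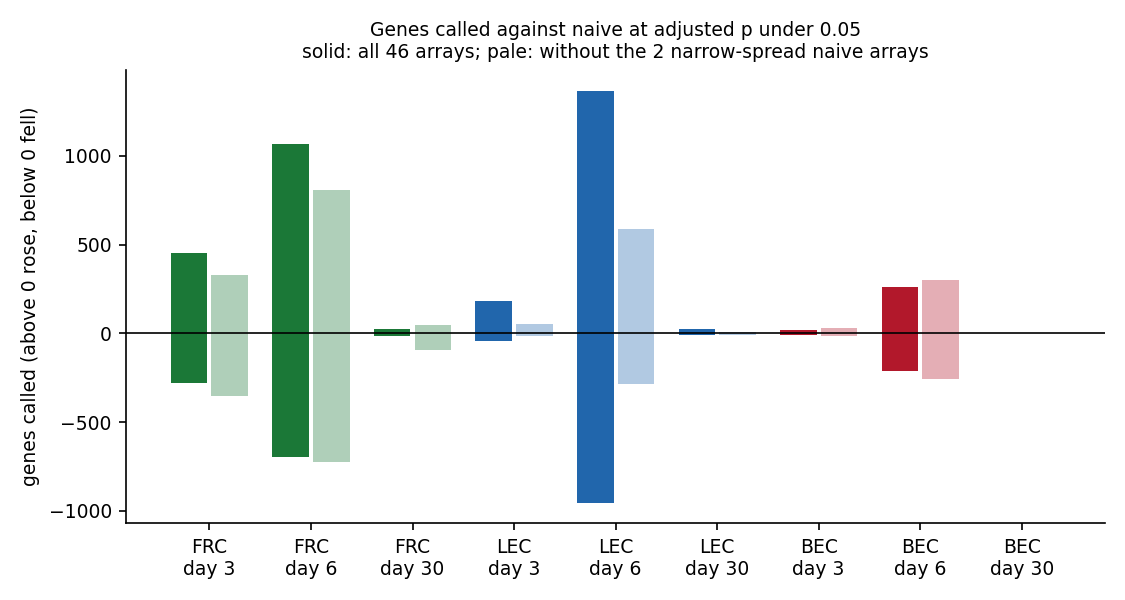
Genes called against naive in each cell type at days 3, 6 and 30, with rises above 0 and falls below 0 on a linear axis of gene counts; solid bars use all 46 arrays and pale bars leave out the 2 naive arrays of narrow spread. LEC at day 6 goes from 2320 to 874 genes, FRC at day 6 from 1763 to 1529 and BEC at day 6 from 474 to 557.

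The response at day 6 overlapped between the cell types. LEC and FRC shared 376 risen genes, where independent draws would give 109.8 (Fisher's exact p = 4.3e-120), BEC and FRC shared 137 (21.1; exact p = 1.2e-80), and BEC and LEC shared 145 (27.1; exact p = 1.4e-74). In all, 102 genes rose in all 3 cell types, among them Zbp1, Gbp4, Cd74, H2-Aa, Tap1, Mki67, Top2a and Vcan, and 24 fell in all 3, among them Fos, Junb, Nr4a1, Icam1, Nfkbia and Apoe. Genes are not independent of each other, which these p-values do not account for. The naive groups of FRC and LEC also each hold 1 array of narrow spread. Those 2 arrays lay alike on the third principal component (62.6 for FRC naive replicate 5 and 63.3 for LEC naive replicate 3). Part of the overlap of LEC and FRC may come from them, and it was not recomputed without them. At day 3, 2 genes rose in all 3, Ifi27l2a and the calcium-binding protein S100a11, which was chosen after its values were seen.

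**Figure D3:**
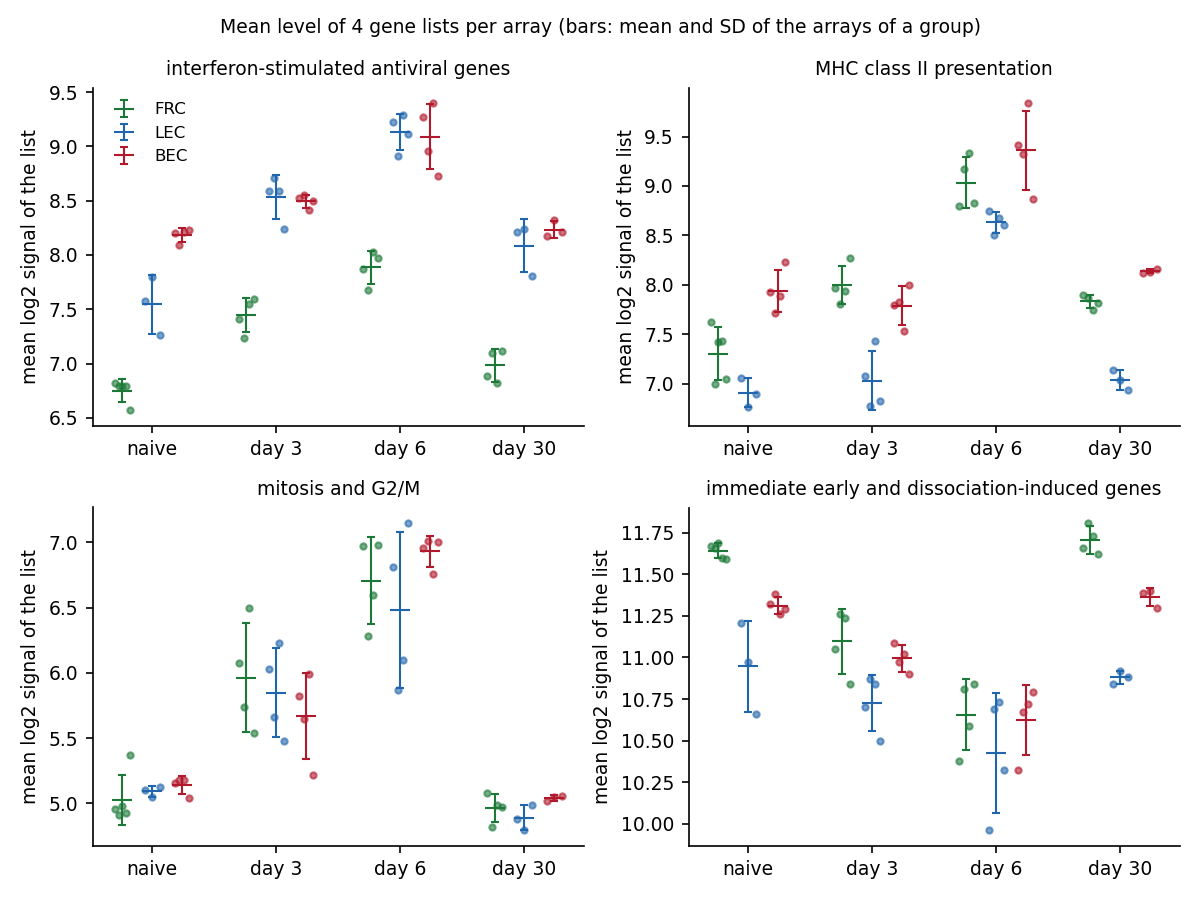
Mean log2 signal over the measured members of 4 gene lists (interferon-stimulated antiviral genes, MHC class II presentation, mitosis and G2/M, and immediate early and dissociation-induced genes) for each array (points), by time and cell type, with the mean and SD of each group (bars). The antiviral, class II and mitosis lists are highest and the immediate early list is lowest at day 6 in each cell type, where 19, 32 and 15 of 33 antiviral genes rose in FRC, LEC and BEC.

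The interaction test asked whether the change from naive differed between the cell types. At day 3 it called 52 genes. Saa3 changed by 4.26 in FRC, 0.08 in LEC and 0.16 in BEC (adjusted p of the interaction 4.85e-06), Cyp2f2 by -4.06, -0.36 and 0.16 (8.88e-09), and Chl1 by 2.95, -0.01 and 0.08 (1.24e-06). Ccl20 changed by 1.88, 3.16 and -0.03 (4.65e-05), and the integrin chain Itga2b by -0.32, 1.31 and -0.19 (4.65e-05). Mctp1 changed by 2.48 in BEC, -0.07 in FRC and -0.12 in LEC (8.88e-09). Each of the 8 named genes kept its call without any 1 array. The count was 102 without FRC naive replicate 5 and 157 without LEC naive replicate 2, and 79 without the 2 arrays of narrow spread.

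At day 6, 668 genes were called by the interaction test. Aoc1 changed by 2.99 in FRC, -0.08 in LEC and -0.03 in BEC (3.81e-15), Inmt by -3.72, 0.16 and -0.37 (1.86e-10), and the fibril-associated collagen Col12a1 by 2.51, -1.24 and 0.35 (8.98e-10). Thbs1 changed by 2.39 in LEC, -0.36 in FRC and 0.04 in BEC (9.33e-10), Ube2ql1 by 3.33, -0.14 and 0.34 (1.79e-09), and Cyp8b1, an enzyme of bile acid synthesis, by 2.48, -0.09 and 0.29 (1.21e-08). Mctp1 changed by 2.91 in BEC, -0.01 in FRC and -0.24 in LEC (2.22e-11). The 8 named genes kept their calls without any 1 array and without the 2 arrays of narrow spread. The count was 1850 without LEC naive replicate 2.

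**Figure D4:**
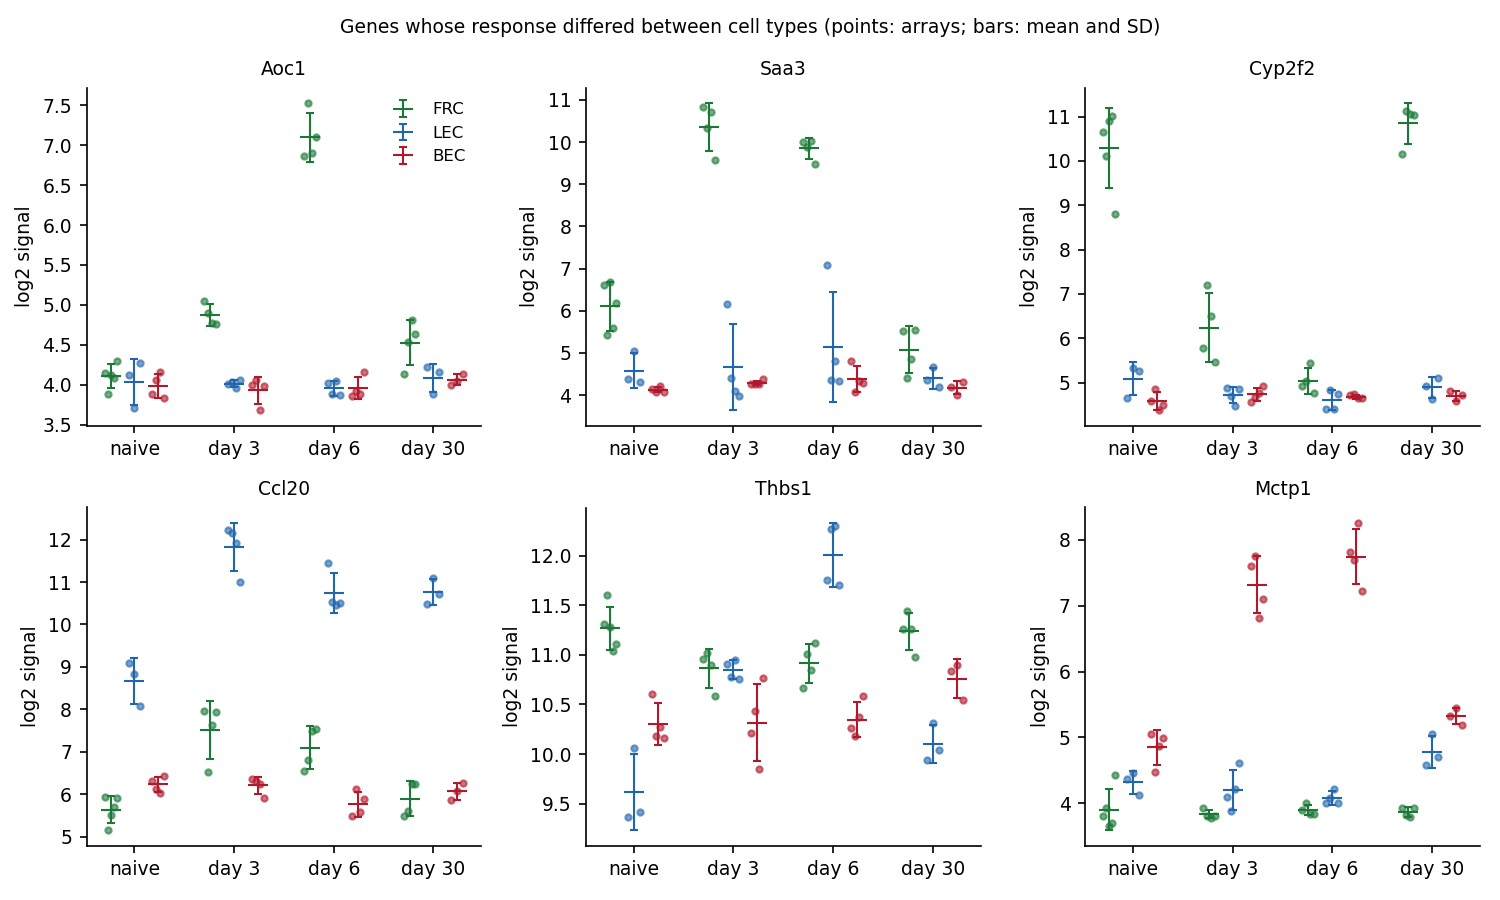
Log2 signal of 6 genes named by the interaction test for each array (points), by time and cell type, with the mean and SD of each group (bars). Saa3 and Cyp2f2 change in FRC at day 3 (4.26 and -4.06) and Aoc1 in FRC at day 6 (2.99), Ccl20 changes most in LEC at day 3 (3.16), Thbs1 in LEC at day 6 (2.39) and Mctp1 in BEC at day 6 (2.91).

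At day 30, 4 genes were called by the interaction test, each with an adjusted p of 0.0452. Atp8b1 changed by 1.07 in FRC, -0.63 in LEC and 0.29 in BEC, Ccin by 0.21, -1.49 and -0.08, Mn1 by 1.14, -0.28 and -0.56, and Osr2 by 1.18, -0.44 and 0.05. Mn1 lost its call when any 1 of 13 of the 22 arrays was left out, and Atp8b1, Ccin and Osr2 when any 1 of 15 was. The count was 718 without LEC naive replicate 2, 36 without FRC naive replicate 5, 10 without FRC day 30 replicate 3 and 7 without BEC naive replicate 1. It was 2 without LEC day 30 replicate 3 and 1 without LEC day 30 replicate 2 or BEC day 30 replicate 2. It was 0 without any 1 of FRC naive replicates 1 to 4, FRC day 30 replicate 4, LEC naive replicate 1, LEC day 30 replicate 1, BEC naive replicate 4 or BEC day 30 replicates 1 and 3.

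List responses were also compared between cell types, and 46 of 297 interaction tests were called at the preset correlation and 0 with an estimated one. Antiviral genes changed less in BEC than in LEC at day 3 (median difference -0.74, adjusted p = 1.9e-09; adjusted p = 0.44 with an estimated correlation) and at day 6 (-0.67, adjusted p = 9.7e-05; 0.73 with an estimated correlation). They changed more in LEC than in FRC at day 6 (0.39, adjusted p = 0.0057; 0.76 with an estimated correlation). Mitosis and G2/M genes changed more in BEC than in LEC at day 6 (0.43, adjusted p = 0.014; 0.83 with an estimated correlation), and class II genes less in BEC than in FRC at day 3 (-0.72, adjusted p = 0.00036; 0.44 with an estimated correlation). Immediate early and dissociation-induced genes fell less in LEC than in FRC at day 6 (0.40, adjusted p = 0.00092; 0.75 with an estimated correlation). Neutrophil markers were lower in FRC at day 6 and differed from the change in LEC (3.32, adjusted p = 0.042; 0.73 with an estimated correlation) and in BEC (2.60, adjusted p = 0.026; 0.73 with an estimated correlation).

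Genes called in the same direction at day 6 and day 30 numbered 14 in FRC, 7 up and 7 down, where independent draws would give 2.09 and 0.84. They included Sfrp4 (2.74 at day 6 and 2.33 at day 30), Atp8b1 (1.32 and 1.07), Adgrg2 (-2.54 and -1.63) and Fosl1 (-2.80 and -1.57). Both comparisons share the naive arrays; with the naive FRC arrays split between them, 5 to 14 genes were shared over 10 splits. Over all genes the FRC changes at days 6 and 30 had a covariance of 0.018, against 0.029 in simulated groups with no change that share naive arrays. Genes are not independent replicates. In LEC, 27 genes were called at both days, 20 up and 7 down, such as Ccl20 (2.07 and 2.10). The covariance was 0.163 against 0.048 simulated. With the 3 naive LEC arrays split into 2 and 1, the lone array being assumed to vary like the other groups, 0 to 106 genes were shared over 6 splits. In BEC 0 were, with 0 called at day 30. The FRC count was 35 without FRC naive replicate 5 and 42 without both arrays of narrow spread. The LEC count was 6, 1644 and 6 without LEC naive replicates 1, 2 and 3, 3 without LEC day 30 replicate 1 or 2, and 8 without both arrays of narrow spread. The BEC count was 2 without BEC day 30 replicate 3 and 1 without BEC day 6 replicate 2.

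Some of the fixed lists shifted in no comparison of a day with naive. The lowest adjusted p of their 9 tests was 0.22 for homeostatic chemokines and lymphocyte survival factors, 0.082 for matrix proteases and inhibitors, 0.33 for angiogenic signalling, 0.091 for high endothelial venule genes, 0.085 for lymphatic endothelial markers, 0.22 for plasma cell markers, 0.060 for macrophage and dendritic cell markers, 0.19 for skeletal muscle markers and 0.52 for keratinocyte markers. Of all 297 list tests, 93 were called at the preset correlation and 25 with an estimated one.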

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

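The patterns weighed here were noticed in these data, and each test was set out before its own result was seen. An array was set apart when its gap to the nearest other array of its group, as a share of the group's range, exceeded Dixon's 95% critical value for groups of 4 to 10 arrays. Over 41 measures this happened in 24 of 369 groups, and chance sets apart about 1 group in 20.

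FRC naive replicate 5 lay apart in 6 measures: the SD of its values (1.83; other arrays 1.99 to 2.04), the median of FRC-specific genes (9.31; 10.17 to 10.34), and the means of antiviral genes (6.57; 6.79 to 6.82), mitosis genes (5.37; 4.91 to 4.98), complement and acute-phase genes (8.55; 9.14 to 9.33) and ER chaperones (8.63; 9.32 to 9.52). FRC day 6 replicate 4 lay apart in the median of endothelial genes (8.10; 5.37 to 5.83), lymphatic endothelial markers (7.27; 5.39 to 5.43) and pan-endothelial markers (7.44; 6.00 to 6.18). LEC day 3 replicate 4 lay apart in SD (1.94; 2.04 to 2.05) and ER chaperones (9.03; 9.49 to 9.54). BEC day 3 replicate 3 stood high in FRC markers (6.81; 5.91 to 6.01) and BEC day 3 replicate 4 low in ER chaperones (9.24; 9.50 to 9.53).

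The other arrays set apart, by list mean, were FRC day 3 replicate 3 for contractile genes (9.21; all others 8.98) and adipocyte markers (5.82; 5.64 to 5.66), FRC day 6 replicate 1 for inflammatory chemokines and cytokines (8.39; 8.91 to 8.95), and FRC day 6 replicate 2 for platelet and erythroid markers (6.07; 5.66 to 5.72). In LEC it was day 6 replicate 1 for class I presentation (10.08; 9.88 to 9.91). In BEC they were naive replicate 4 for mitosis genes (5.04; 5.16 to 5.18), naive replicate 2 for contractile genes (6.95; 7.37 to 7.43), naive replicate 3 for clock genes (7.27; 7.13 to 7.15) and for platelet and erythroid markers (5.61; 5.78 to 5.81), day 6 replicate 4 for B cell markers (5.76; 5.25 to 5.33) and day 3 replicate 2 for skeletal muscle markers (5.55; 5.66 to 5.67).

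The change from naive differed between the cell types in 52 genes at day 3, 668 at day 6 and 4 at day 30. The adjusted p of the interaction at day 3 was 8.88e-09 for Cyp2f2 and for Mctp1, 1.24e-06 for Chl1, 4.85e-06 for Saa3, 4.65e-05 for Ccl20 and for Itga2b, 0.000488 for Inmt and 0.000519 for Cyp2e1. At day 6 it was 3.81e-15 for Aoc1, 4.32e-12 for Cyp2f2, 2.22e-11 for Mctp1, 1.86e-10 for Inmt, 8.98e-10 for Col12a1, 9.33e-10 for Thbs1, 1.79e-09 for Ube2ql1 and 1.21e-08 for Cyp8b1. At day 30 it was 0.0452 for each of Atp8b1, Ccin, Mn1 and Osr2.

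Probe sets that the comparisons of genes left out also held calls against naive. Of 805 with several gene symbols, 53, 159 and 3 were called in FRC at days 3, 6 and 30, 33, 183 and 5 in LEC, and 22 and 9 in BEC at days 6 and 30. Of 7293 without a name here, 26, 219 and 5 were called in FRC, 16 and 330 in LEC at days 3 and 6, and 2, 48 and 1 in BEC.

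Most LEC day 6 calls were lost without the 2 naive arrays of narrow spread, FRC naive replicate 5 and LEC naive replicate 3, with 1505 lost and 815 kept; without LEC naive replicate 3 alone, 734 genes were called. Of the lost genes, 89.8% changed in the direction predicted by their slope on array spread within the FRC and BEC groups, and of the kept genes 72.3% did, so array quality may account for part of the 2320 calls. The mean array SD was 2.06 at LEC day 6 and 1.93 in naive LEC. Of the lost genes, 61.4% changed in the same direction in BEC at day 6, against 78.5% of the kept genes, which leaves open a response that fewer naive arrays miss. The median size of the lost changes was 0.74 log2 units with all arrays and 0.51 without the narrow ones.

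Genes of the other gates were tested in 2 groups, not in BEC at days 3 and 30, where FRC markers also shifted up (0.23 and 0.33). In BEC at day 6, 82.9% of 82 FRC-specific genes were higher than in naive BEC and 11 were called. Their median of 0.29 lay at percentile 100 of random lists matched on level (-0.01 to 0.09). In FRC at day 30, 90.9% of 11 endothelial genes were higher but only 1 was called. Their median of 1.01 also lay at percentile 100 (-0.10 to 0.21). Both sets differ at least 16-fold between naive groups here, which are also the baseline, so the choice favours rises and array spread stays open. A candidate is RNA of the other cell type (median 1.20% FRC RNA in BEC, 1.76% BEC RNA in FRC), though the gp38 and CD31 gates should remove such cells. A change of expression within the sorted cells was not tested.

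Immediate early genes were called lower at day 6 in 3 of 3 cell types. Without the 2 narrow arrays the median change in FRC and LEC was at least 96.1% of that with all arrays, which argues against array spread. Handling at isolation that differed between naive and infected mice could also lower these genes. It cannot be told apart from infection, since the 2 are confounded in this design.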

How the results depend on the processing

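All alternatives were chosen before the data were examined except leaving out the 2 narrow arrays and the array SD covariate, chosen after. Signal over background limits dim genes: 13239 genes were tested here, 19937 with no filter and 8155 with the stricter one. Counts are of genes called ("interaction" where the response differed between cell types), given where they moved by over 1.5 times. Fitting only the cell types compared together gave 290, 1129 and 2 in FRC at days 3, 6 and 30, and 56, 1011 and 0 in LEC. It gave 28 in FRC and 139 in LEC for day 6 against day 3, and 1 (FRC) and 0 (LEC) at both days 6 and 30. Such fits have fewer residual degrees of freedom, yet BEC gave 28 and 618 at days 3 and 6 (joint fit 26 and 474). Fewer degrees alone do not explain the lower FRC and LEC counts. The joint fit pools spread over cell types, so its FRC and LEC p-values may be too small. Array weights gave 65 in FRC at day 30, 5031, 6806 and 5183 in LEC, 177, 829 and 17 in BEC, 457 (LEC) and 250 (BEC) for day 6 against day 3, 7064 and 6967 for naive FRC and naive BEC against LEC, interaction counts of 2229, 4071 and 3538, and 22, 3917 and 5 at both days in FRC, LEC and BEC. The weights did not converge fully and put 12.2 on LEC naive replicate 1. Cyclic loess gave 141 and 1532 in LEC at days 3 and 6, 46 in BEC at day 3 and 7 for the day 30 interaction. Median centring gave 20 in LEC at day 30, 0 for the day 30 interaction and 17 at both days in LEC. No filter gave 0 for the day 30 interaction and 41 at both days in LEC, and the stricter filter 0 for the day 30 interaction. Replicate number as a term gave 93 in FRC at day 30, 389 and 106 in LEC at days 3 and 30, interaction counts of 99 and 48 at days 3 and 30, and 36 (FRC) and 80 (LEC) at both days. Time and number as a random effect (correlation 0.057) gave 11 for the day 30 interaction and 41 at both days in LEC. Without the 2 narrow arrays the counts were 140 in FRC at day 30, 66, 874 and 16 in LEC, 42 and 1 in BEC at days 3 and 30, 1640 for naive LEC against BEC, 79 and 16 for the interaction at days 3 and 30, and 42 (FRC) and 8 (LEC) at both days. The array SD covariate gave 75 in FRC at day 30, 92, 724 and 4 in LEC, 68 in BEC at day 3, 175 in FRC for day 6 against day 3, 1664 for naive LEC against BEC, 87 for the day 3 interaction and 2 at both days in LEC. Apart from fewer arrays or genes where named, the cause was not tested.

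Leaving out 1 array at a time gave lowest and highest counts of 366 and 816 in FRC at day 3, 1283 and 1815 at day 6, and 25 and 91 at day 30. In LEC they were 51 and 1434, 734 and 4253, and 3 and 2030, and in BEC 15 and 27, 370 and 432, and 0 and 2. For day 6 against day 3 they were 78 and 163 in FRC, 209 and 276 in LEC, and 65 and 92 in BEC. For naive cells they were 2285 and 4161 (FRC and LEC), 2958 and 3242 (FRC and BEC), and 1491 and 4389 (LEC and BEC). The interaction gave 44 and 157 at day 3, 535 and 1850 at day 6, and 0 and 718 at day 30. Genes called at both days 6 and 30 gave 10 and 35 in FRC, 3 and 1644 in LEC, and 0 and 2 in BEC. For LEC at days 3, 6 and 30 against naive the highest counts came without LEC naive replicate 2, and the lowest at days 3 and 6 without LEC naive replicate 3.

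Of the 93 list shifts, 25 stayed called with an estimated correlation, 78 with cyclic loess, 74 with the array SD covariate, 81 without the narrow arrays, 84 with array weights, 90 with median centring, 87 with no filter, 74 of 83 with the stricter filter, and 93 with the intensity trend or probe set means. Among lists that stayed called without the narrow arrays, medians moved by over 1.5 times for complement and acute-phase genes in FRC at day 6 (0.70 to 0.37), ER chaperones in FRC at days 6 (0.37 to 0.22) and 30 (-0.19 to -0.30) and in LEC at days 3 (0.47 to 0.28) and 6 (0.46 to 0.29), pan-endothelial markers in FRC at day 30 (0.36 to 0.55), and in LEC the interferon-gamma-inducible GTPases and related genes (0.98 to 0.59) and immediate early genes (-0.18 to -0.33) at day 3 and matrix genes at day 6 (0.18 to 0.37). Another 6 list shifts, not called with all arrays, were called without those 2: in LEC matrix genes at day 3 (adjusted p = 0.0062), FRC markers at day 6 (0.016), and mitosis (0.028) and immediate early genes (0.0028) at day 30, and in BEC ER chaperones at day 3 (0.044) and B cell markers at day 30 (0.041). With 1 array left out, 676 of 734 list tests stayed called. The direction of the list test and the median both reversed for ER chaperones in LEC at day 30, from 0.31 to -0.03 with cyclic loess (adjusted p = 0.69) and -0.14 with the array SD covariate (adjusted p = 0.041). The median alone changed sign for class I presentation in LEC at day 30 (0.33 to -0.02 with cyclic loess), complement and acute-phase genes in FRC at day 3 (0.20 to -0.05 without the narrow arrays, or without FRC naive replicate 5 alone), matrix genes in LEC at day 6 (0.18 to -0.02 without LEC naive replicate 2) and inflammatory chemokines and cytokines in BEC at day 6 (-0.08 to 0.01 without BEC day 6 replicate 1). The cause was not tested. Named genes reversed in 0 of these settings. They stayed called in 359 of 480 cases with only the cell types compared in the fit, 454 of 500 with cyclic loess, 451 without the narrow arrays, 444 with the array SD covariate and 3813 of 4325 with 1 array left out. Replicate numbers were checked for pairing. Across cell types, 10 of 43 pairs with the same number correlated above 0.1 (-0.29 to 0.25). Between naive and a day, 6 of 32 did (-0.32 to 0.33). The LEC array of the same number was the best match for 3 of 4 BEC arrays at day 3. It was so for 2 of 4 at day 6, 3 of 3 at day 30 and 0 in the naive group. A pairing of cell types within a day therefore cannot be excluded, and the main fit treats the arrays as unpaired.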

Other observations

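The split of FRC day 30 without the narrow array and the splits that count LEC calls shared with FRC or BEC were chosen only after the results with all arrays were seen. Lists without a shift as a whole still held called genes at day 6. Of 19 homeostatic chemokines and survival factors, 5 rose and 2 fell in FRC, 2 rose and 3 fell in LEC, and 1 rose and 2 fell in BEC. In FRC, the lymphocyte growth factor Il15 rose by 2.05 ± 0.40 and the alarmin Il33 by 1.70 ± 0.38, while Flt3l fell by 1.11 (SE 0.19) and the adhesion molecule Icam1 by 1.01 (SE 0.14). Icam1 also fell in LEC (-0.78 ± 0.16) and BEC (-0.77 ± 0.15), and Csf1 fell in LEC (-0.92 ± 0.19).

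Of 18 matrix proteases and inhibitors, 4 rose and 1 fell in FRC, 5 rose in LEC, and 1 rose and 1 fell in BEC. Timp1 rose by 2.31 ± 0.40 and Mmp3 by 1.35 ± 0.27 in FRC, and Adamts5 rose by 3.08 ± 0.31 and the plasminogen activator Plau by 2.55 ± 0.41 in LEC. Among angiogenic genes in LEC, Angpt2 rose by 1.92 ± 0.39 and Pdgfb by 1.14 ± 0.26, and Vegfa fell by 0.95 (SE 0.21). In BEC, Esm1 (-1.71 ± 0.25) and the Notch ligand Dll4 (-0.94 ± 0.22) fell. Among high endothelial venule genes in LEC, Podxl rose by 1.99 ± 0.31 and the sulfotransferase Chst2 fell by 0.95 (SE 0.20). Blood endothelial markers, of which Podxl is 1, had 4 of 11 up in LEC, with Aqp1 at 2.27 ± 0.23, and no shift as a list (median 0.51, adjusted p = 0.21); their mean was 7.71 to 7.92 in the day 6 arrays and 7.09 to 7.45 in the naive ones.

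The arrays of each comparison were split in other ways into groups of the same sizes. Chance can be excluded for FRC at day 3 (734 genes; highest other 441) and day 6 (1763; 1099), each in 1 of 100 splits, and for BEC at day 3 (26; 5) and day 6 (474; 16), each in 1 of 35. It can be excluded for day 6 against day 3 in FRC (105; 26), LEC (295; 38) and BEC (110; 10), each in 1 of 35, and for naive FRC against BEC (3350; 2654; 1 of 100) and naive LEC against BEC (2765; 1322; 1 of 35). For naive FRC against LEC it can be excluded with 2 of 56 splits as large, although the highest other split (5495 against 3111) exchanged FRC naive replicate 5 and LEC naive replicate 2.

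By the number of genes called, chance cannot be excluded for LEC at day 3 (5 of 35 splits as large; 225 genes, highest other 3056) or day 6 (2 of 35; 2320, 2375). For LEC day 6 genes also called in the same direction in FRC (473, highest other 274) or BEC (191, 70), 1 of 35 splits each was as large. This count was chosen after the totals were seen, so chance is not excluded. Nor is it at day 3, with 2 of 35 splits as large for FRC (50, 138) and 2 for BEC (5, 10). Nor can it be for FRC at day 30 (9 of 100; 42, 586) or the interaction at day 3 (11 of 100; 52, 2415) and day 30 (9 of 100; 4, 1647). Splits with several times the real count point to a structure of the samples. The highest LEC splits at days 3 and 6 put LEC naive replicate 2 with 3 day arrays and the other naive arrays with 1. The highest FRC day 30 split put FRC naive replicate 5 with day 30 replicates 1, 3 and 4. Without that naive array, left out only after these splits were seen, 91 genes were called in FRC at day 30. For this reason 1 of 35 splits as large (highest other 18) does not exclude chance. For LEC at day 30 the 10 splits are too few for a share under 0.05 (34 genes, highest other 304; 2 splits as large). In BEC at day 30 limma called 0 genes (644 at an unadjusted p under 0.05), so all 35 splits are as large and say nothing (highest other 3).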
